A study of Homo sapiens with 6 samples.

How the data were processed

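Click-seq peak lists were used from MV4;11 cells treated with JQ1, JQ1-PA or JQ1-TCO. Per the labels' protocols, chromatin came from formaldehyde-fixed, sonicated cells and was precipitated on beads through biotin. Reads were aligned with BWA 0.6.2-r126 to hg19 and peaks were called with MACS2, per the submitters' processing notes, which give no MACS2 version. Each library had its own list, and the background library used for calling is not given in the sources used here. The names inside the lists of JQ1-PA replicate 2 and of both JQ1-TCO libraries record trimming, sorting and removal of duplicates, and the names in the other lists do not, so the lists may not have been made alike.

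The lists of unmodified JQ1 and JQ1-PA replicate 1 have 5 columns, and the deposited score in the fifth is of a kind the file does not state. The other lists have 10 columns. In these the deposited score was 10 times the −log10 q of the peak, cut to a whole number, and the authors' files also give −log10 p, a fold enrichment (a ratio to the caller's background) and the peak summit. Scores and folds are the authors' own values, and were used only to describe, rank or filter peaks within a list. No list had a score under 1.3, which is −log10 of 0.05, when the −log10 q was taken for the longer layout. No peak passed the end of an hg19 chromosome.

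Peaks were counted as shared when they overlapped by at least 1 bp. Chance overlap was taken from 100 circular shifts of each list along chromosomes 1 to 22, X and Y, with lengths from GenomeInfoDb 1.38.1 in R 4.3.3. The peaks of the 4 clickable libraries were merged into regions, and clusters were made by joining peaks within 12.5 kb. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The interval code was tested on simulated data, where 12000 regions were all given the right combination of libraries, and shifted random lists overlapped at 6.744% against 6.742% by calculation. Intervals are exact Clopper-Pearson 95% intervals and cover counting error only. Sequencing depth is unknown, because the lists give no read counts.

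Samples were grouped by their labels. The main comparisons, the rule for naming regions and the alternatives were fixed before the data were examined. A local shift of 100 kb was added after seeing the data. So was the use of chromosomes 1 to 22 and X for the regions of 1 compound. The plan did not list peak density per chromosome, sharing by score class, summit distances or score percentiles of kinds of region. Nor did it list clusters that ranked differently between libraries, or groups of unmodified JQ1 peaks. The rule took the 10 regions with the highest lowest score percentile over the 4 clickable libraries, the 10 clusters with the best mean rank, up to 5 regions per compound that were absent from the other, and up to 10 unmodified JQ1 peaks by score. Promoter shares and gene lists had been planned for the case that an hg19 annotation was given. The gene table at hand is on GRCh38, so these were not run and no coordinates were converted. The alternatives were a stricter overlap of 50%, lists of equal length, the upper 50% of each list by score, chromosomes 1 to 22 and X, other stitching distances, ranking clusters by summed score, leaving out peaks of unmodified JQ1, and leaving out each library in turn. The input DNA sample was not analysed here.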

Results

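Click-seq maps where a small molecule sits on chromatin. A drug analogue carrying a reactive handle is coupled to biotin by a click reaction, and the DNA of the precipitated chromatin is sequenced. The molecule here was JQ1, which binds the acetyl-lysine pockets of the BET bromodomain proteins. The cells were MV4;11, an established human acute leukaemia line that carries an MLL rearrangement. The study held 6 samples. JQ1-PA, a JQ1 analogue with a propargyl (alkyne) handle, was represented by 2 libraries, and JQ1-TCO, an analogue with a trans-cyclooctene handle, by 2 more. Unmodified JQ1, which has no handle and is the control for pull-down without a click reaction, was represented by 1 library. The input DNA sample was not analysed here. All values below come from the 5 peak lists, 1 per library. The lists give no read counts, so the sequencing depth behind them is unknown. Nothing in the labels says that the replicates came from separate cultures. The names inside the list of JQ1-TCO replicate 2 carry extra words that appear to refer to lysis and that replicate 1 lacks, so the 2 libraries may differ in protocol although the labels number them as replicates.

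The first question was how much chromatin each molecule recovered. The clickable molecules gave between 25397 and 63569 peaks per library, and unmodified JQ1 gave 142. The 2 JQ1-PA libraries held 25397 and 57594 peaks, and the 2 JQ1-TCO libraries held 60414 and 63569. Peaks covered 12.77 Mb and 23.95 Mb of the genome with JQ1-PA, 32.175 Mb and 40.155 Mb with JQ1-TCO, and 0.074 Mb with unmodified JQ1. The median peak width was 364 bp and 271 bp for JQ1-PA, 306 bp and 376 bp for JQ1-TCO, and 369 bp for unmodified JQ1. Peaks of 5 kb or more numbered 12 and 7 in the JQ1-PA lists and 55 and 119 in the JQ1-TCO lists. The 2 JQ1-PA libraries differed from each other by more than the JQ1-TCO libraries did, in peak number and in covered length. With 2 libraries against 2, an exact permutation test cannot give a two-sided p below 0.33, so no test between the compounds was made. JQ1-PA replicate 2 and both JQ1-TCO lists also hold peaks on unplaced contigs, 250, 123 and 136 of them, whereas the lists of JQ1-PA replicate 1 and unmodified JQ1 hold none.

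**Figure D1:**
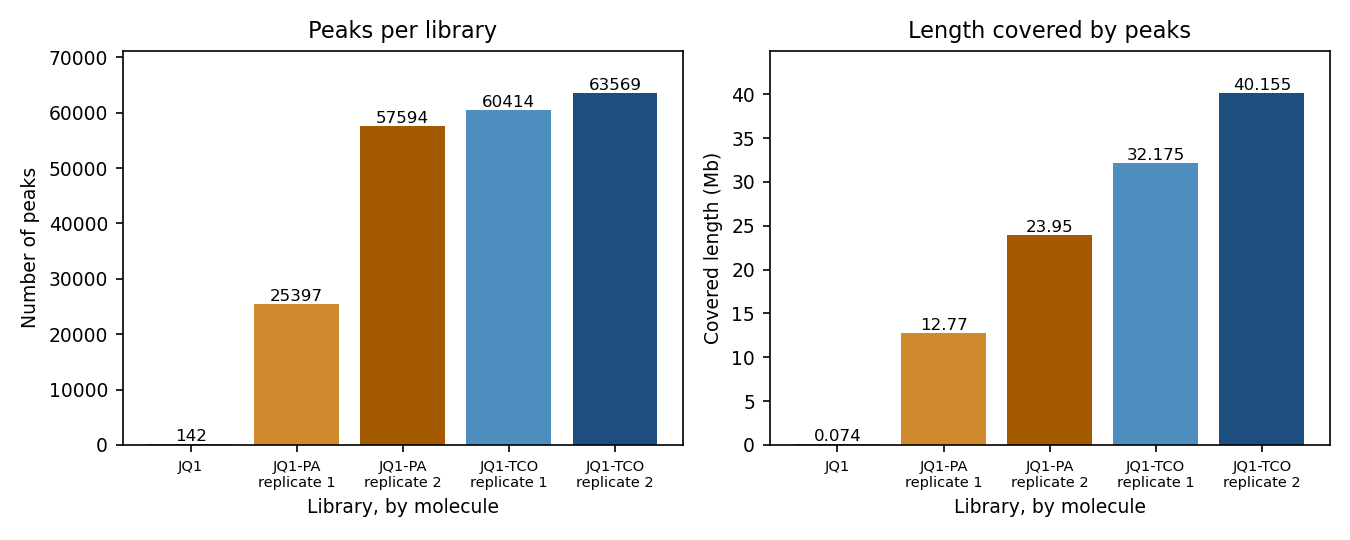
Bars give the number of peaks (left) and the length they cover in Mb (right) for each of the 5 libraries, with no error bars because each bar is 1 library. Unmodified JQ1 has 142 peaks, against 25397 to 63569 in the clickable libraries.

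Peaks were unevenly spread over the chromosomes. Chromosome 19 had the highest peak density in each of the 4 clickable libraries, at 31.5, 92.9, 71.3 and 80.8 peaks per Mb for JQ1-PA replicates 1 and 2 and JQ1-TCO replicates 1 and 2. This was 3.84, 5.02, 3.66 and 3.95 times each library's density over all chromosomes. Unmodified JQ1 had 18 of its 142 peaks on chromosome 19, 6.64 times its own density over all chromosomes. Of these 18, however, 15 lay between 35788904 and 37786367, so this excess was largely that of a single locus. Input DNA was not analysed here. In the clickable libraries, chromosome 17 followed at 2.24 to 2.45 times that density, against 1.07 times with unmodified JQ1. Chromosome 4 lay at 0.41 to 0.52 times with the clickable molecules and at 1.82 times with unmodified JQ1. Of the 16 unmodified JQ1 peaks there, 14 lay between 49104355 and 49652857. Chromosome X lay at 0.34 to 0.54 times in the clickable libraries, the lower end being JQ1-PA replicate 2, and unmodified JQ1 had no peak on it. Chromosome Y was the sparsest in every clickable library, at 0.5 to 1.4 peaks per Mb. It held 15 of the 142 unmodified JQ1 peaks, 11 of them between 58825358 and 58916855. Chromosome 8 was close to the mean in these libraries, from 0.82 times in JQ1-PA replicate 1 to 1.08 times in replicate 2.

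The second question was whether the libraries marked the same places. Of the JQ1-PA replicate 1 peaks, 67.6% overlapped a JQ1-PA replicate 2 peak, 86.9% a JQ1-TCO replicate 1 peak and 90.4% a JQ1-TCO replicate 2 peak. The exact Clopper-Pearson 95% intervals were 67.1 to 68.2%, 86.4 to 87.3% and 90.0 to 90.8%; like all intervals here, they cover counting error only. At this 1 bp overlap, JQ1-PA replicate 1 shared more of its peaks with either library of the other compound than with the other library of its own. When 50% of both peaks had to overlap, this no longer held: the shares were 37.5%, 38% and 31.8% in the same order. Of the JQ1-PA replicate 2 peaks, 47.8% overlapped JQ1-TCO replicate 1 and 49.8% overlapped JQ1-TCO replicate 2. The 2 JQ1-TCO libraries shared 72.5% of replicate 1 peaks. When each list was moved around its chromosomes at random, 100 times, the mean overlap for these 6 pairs was 2.24 to 2.87%, and the observed overlap was 17.5 to 35.9 times as high. Against lists moved by only 100 kb, which keeps the local density of peaks, it was 7.1 to 14.8 times as high. The order of the pairs also depended on list length. With the 25397 highest-scoring peaks of each library, the JQ1-TCO pair shared most (83.3%) and the JQ1-PA pair least (61.6%), and the mixed pairs lay between, at 77.2% and 82.9% for JQ1-PA replicate 1 and 70.1% and 72.4% for JQ1-PA replicate 2.

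**Figure D2:**
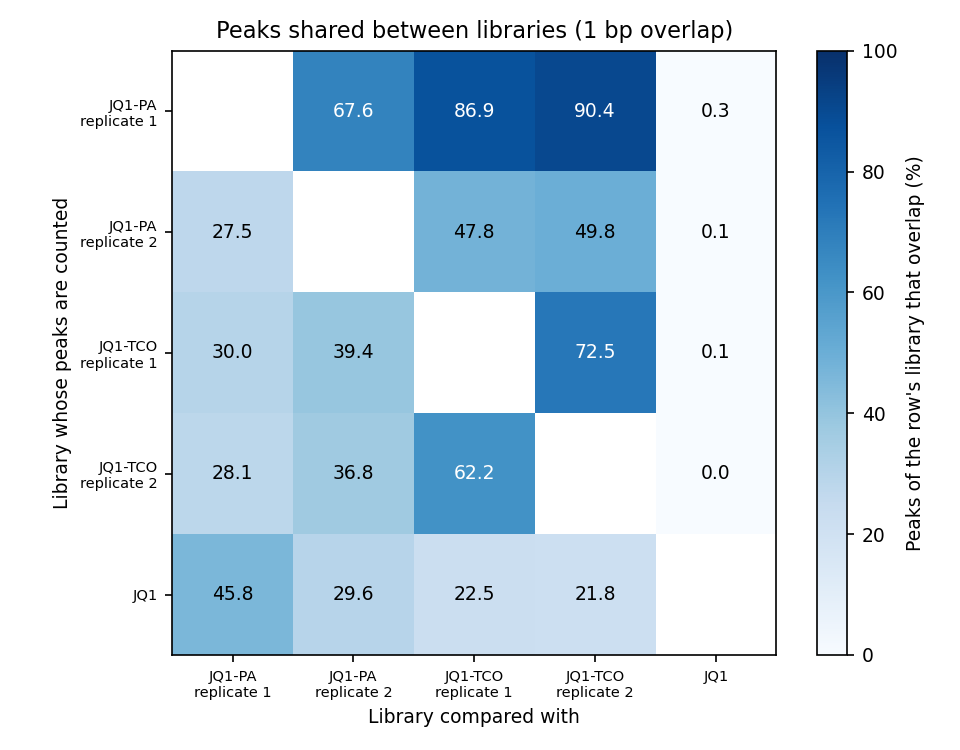
Each cell gives the percent of the row library's peaks that overlap a peak of the column library by at least 1 bp. JQ1-PA replicate 1 overlaps the JQ1-TCO lists at 86.9% and 90.4% and its own replicate at 67.6%.

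Sharing was highest among the peaks to which the peak caller gave the highest scores. In the highest-scoring 10% of each list, between 94.4% and 100.0% of peaks were shared with each other clickable library, whichever the compound. In the lowest-scoring 10%, the shares ran from 2.0% for JQ1-TCO replicate 2 in JQ1-PA replicate 1 to 65.2% for JQ1-PA replicate 1 in JQ1-TCO replicate 2. The rise over score classes was not steady in every list: from the lowest class to the next, the share of JQ1-PA replicate 2 peaks in JQ1-TCO replicate 1 went from 20.7% to 12.0%. Peaks of equal score were placed in classes by genome position, so such a step need not follow score. Among shared peaks, scores ranked alike to different degrees: Spearman's rho across peaks, counted from either list of a pair, was 0.79 and 0.87 between the JQ1-TCO libraries and 0.51 and 0.54 between the JQ1-PA libraries. It was 0.70 and 0.80 between JQ1-PA replicate 2 and JQ1-TCO replicate 1, and 0.68 and 0.82 between JQ1-PA replicate 2 and JQ1-TCO replicate 2. JQ1-PA replicate 1 gave 0.54 and 0.66 with JQ1-TCO replicate 1 and 0.53 and 0.69 with JQ1-TCO replicate 2. Peaks are not independent replicates, so no p-value is attached. Peak summits were compared in the 3 lists that give them. No chance distance was computed, and the overlap required of narrow peaks itself keeps their summits near each other. Over peaks of at most 1 kb that overlapped one to one, the median summit distance was 45 bp between the JQ1-TCO replicates, 58 bp between JQ1-PA replicate 2 and JQ1-TCO replicate 1, and 64 bp between JQ1-PA replicate 2 and JQ1-TCO replicate 2.

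**Figure D3:**
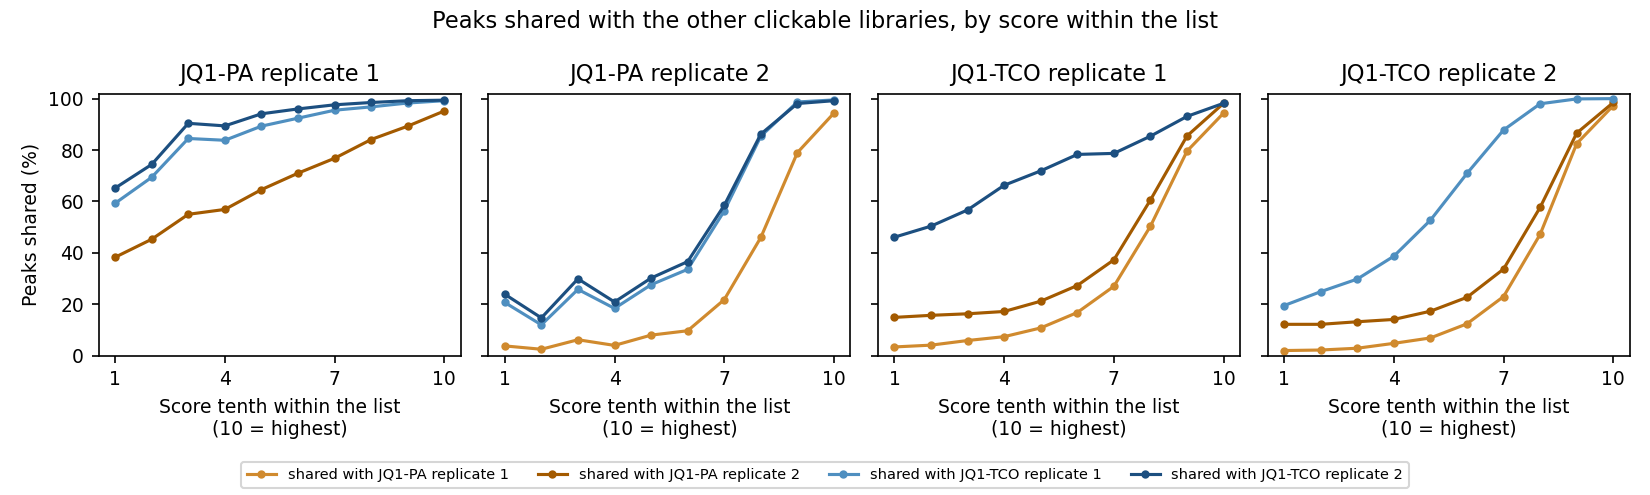
For each clickable library (panel), the percent of its peaks shared with each other clickable library (line) is plotted against the peak's score class within its own list, from 1 to 10, 10 being the highest. All lines reach 94.4% or more in the highest class.

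Merging the peaks of the 4 clickable libraries gave 107898 regions. A peak of all 4 libraries lay in 13381 of them, 12.4%, and these were the widest, with a median of 1330 bp. Regions of 3 libraries numbered 10780 (median width 688 bp), regions of 2 libraries 18245 (391 bp) and regions of a single library 65492 (222 bp). Because overlapping peaks were merged into a region, its width and its number of libraries are tied by construction. JQ1-PA replicate 2 alone accounted for 27326 single-library regions, and JQ1-TCO replicates 1 and 2 for 15013 and 20979. Leaving out JQ1-PA replicate 1, the shortest list, raised the number of regions common to all remaining libraries to 20780. Requiring every library to cover 50% of the region lowered it from 13381 to 5385.

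**Figure D4:**
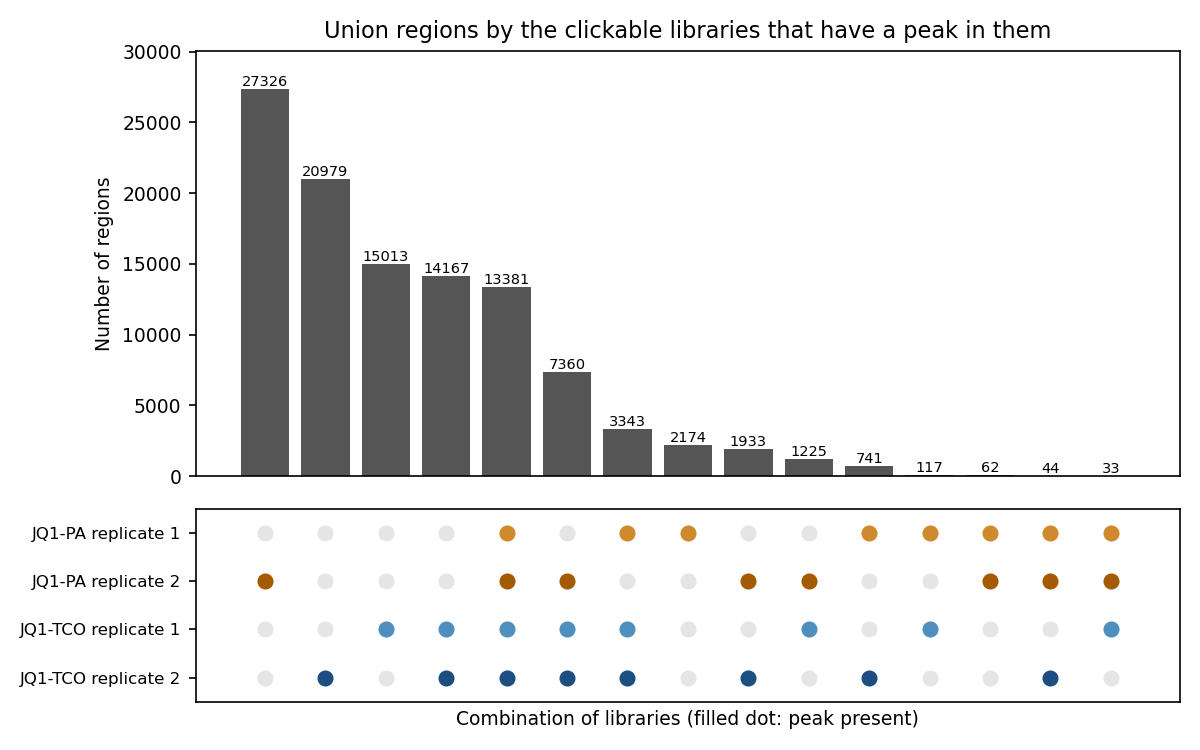
Bars give the number of merged regions for each combination of clickable libraries, and coloured dots under each bar show which libraries have a peak. The JQ1-TCO pair without JQ1-PA holds 14167 regions, and the JQ1-PA pair without JQ1-TCO holds 62.

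The 10 regions ranked highest in all 4 libraries at once, by their lowest score percentile, are given by hg19 position. No hg19 gene annotation was used here, so genes, exons and promoters at these positions are not named. The first was chromosome 19, 47613862 to 47617214 (3353 bp), which was at or above the 99.98th percentile of every list. It was followed by chromosome 19, 41769724 to 41772465 (lowest percentile 99.97), and by chromosome 13, 28711841 to 28716063, and chromosome 2, 3622217 to 3623882 (both 99.96). Chromosome 15, 75492577 to 75496703, stood at 99.94 and chromosome 5, 369958 to 379511, at 99.93; the latter was the widest of the 10 at 9554 bp. The others were chromosome 13, 26795584 to 26797181 (99.91), chromosome 5, 133968065 to 133969361, and chromosome 11, 122932118 to 122934358 (both 99.88), and chromosome 13, 20436687 to 20439219 (99.87). Chromosome 13 therefore held 3 of the 10 regions.

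Neighbouring peaks were joined into clusters, ranked within a library by the length their peaks cover. A stretch of chromosome 5, 342774 to 499734, had the best mean rank: it had rank 1 in JQ1-PA replicate 1, rank 2 in JQ1-PA replicate 2 and JQ1-TCO replicate 1, and rank 3 in JQ1-TCO replicate 2. Peaks covered 30.7% and 33.7% of its 157.0 kb with JQ1-PA and 41.1% and 43.2% with JQ1-TCO, and unmodified JQ1 had no peak there. With only 142 peaks in all, unmodified JQ1 would lack a peak in most stretches of this length. Next came chromosome 21, 45551810 to 45686182, with 17.7% and 29.8% covered with JQ1-PA and 38.3% and 41.8% with JQ1-TCO. Chromosome 8, 142074689 to 142454851, and chromosome 19, 619235 to 1290727, came after it. A 42.1 kb stretch of chromosome 1, 228743995 to 228786104, was the most densely covered of the 10 best in JQ1-PA replicate 2 (79.6%) and in the JQ1-TCO libraries (89.5% and 94.0%), but not in JQ1-PA replicate 1 (27.4%). The remaining clusters of the 10 best lay on chromosome 19 (33726142 to 33802563 and 1730237 to 1947741), chromosome 20 (61264566 to 61470199), chromosome 16 (30345892 to 30681060) and chromosome 5 (881067 to 1012001). The first 100 clusters of the 2 JQ1-TCO libraries had 71 in common, those of the 2 JQ1-PA libraries 28, and the mixed pairs between 47 and 54. Shifted clusters gave means of 0.9 to 3.3. In all 4 libraries, 21 of the first 100 were shared, which became 41 without JQ1-PA replicate 1 and 37 without JQ1-PA replicate 2.

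**Figure D5:**
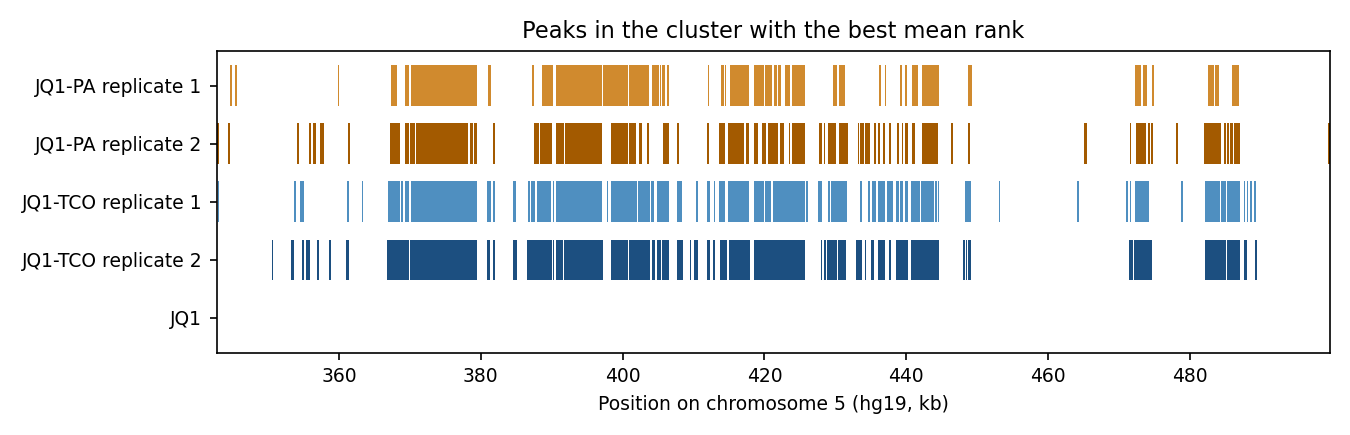
Filled boxes are the peaks of each library along chromosome 5 (hg19, in kb), over the cluster from 342774 to 499734. The peaks of the 4 clickable libraries fall mostly at the same positions, covering 30.7% to 43.2% of the stretch. Unmodified JQ1, with only 142 peaks in all, has none here.

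Some clusters ranked differently between libraries. Each was picked and bounded in a library where it ranked among the highest, and the JQ1-TCO lists covered more of the genome in total. Ranks are given for JQ1-PA replicates 1 and 2 and then JQ1-TCO replicates 1 and 2. The first cluster of both JQ1-TCO libraries was chromosome 16, 11124950 to 11361115 in replicate 1, of which peaks covered 32.1% and 40.1% with JQ1-TCO and 6.6% and 15.4% with JQ1-PA (ranks 173, 10, 1 and 1). The second of JQ1-TCO replicate 2, chromosome 13, 28493950 to 28746620, was covered at 17.2% and 27.2% with JQ1-TCO and at 6.2% and 11.4% with JQ1-PA (ranks 183, 97, 6 and 2). The second cluster of JQ1-PA replicate 1, chromosome 16, 85958125 to 85991945, was covered at 72.9% there and at 6.9% in JQ1-PA replicate 2, with 37.2% and 43.9% in the JQ1-TCO libraries (ranks 2, 3076, 190 and 71). A cluster on contig GL000220.1, 101606 to 161682, was covered at 74.2% in JQ1-PA replicate 2 and at 73.1% and 77.2% with JQ1-TCO (ranks 3, 4 and 7). It had no rank in JQ1-PA replicate 1, whose list holds no contig peaks.

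A further question was whether the handle changed where JQ1 was found. Both JQ1-TCO libraries had a peak and neither JQ1-PA library did in 14167 regions, and the converse held in 62. Together these 14229 regions compare with 2050 and 1966 for the other ways of splitting the 4 libraries 2 against 2. The split by compound was thus the highest of 3, which is the smallest share that this design allows. Its total rested on the JQ1-TCO pair. Every mixed pair had more regions to itself, from 117 to 1933, than the JQ1-PA pair with 62. With the 25397 highest-scoring peaks of each library the counts were 2805 and 137, together 2942, against 696 and 1373 for the other splits. The JQ1-PA pair was again lowest, since the mixed pairs had 158 to 1035 regions to themselves. Without JQ1-PA replicate 1, 17606 regions were found in both JQ1-TCO libraries and not in JQ1-PA replicate 2, while 27404 were found in JQ1-PA replicate 2 and in neither JQ1-TCO library. The latter count asks for a peak in 1 library and the former in 2, so they do not compare the compounds on equal terms. A region took the score percentile of its best peak in a library, which can favour wide regions. Regions of all 4 libraries were wider, with a median of 1330 bp against 400 bp for the 14167. These 14167 regions scored lower than the regions of all 4 libraries. Their median score percentile was 38.2 and 49.9 in JQ1-TCO replicates 1 and 2, against 87.9 and 88.9, and 10 and 7 of them reached the highest-scoring 10%. The leading ones were chromosome 11, 14916436 to 14916918, chromosome 5, 171788317 to 171789035, chromosome 10, 119522347 to 119522915, chromosome 8, 9408548 to 9408943, and chromosome 16, 20924651 to 20926222, at lower percentiles from 88.06 to 89.63. The leading JQ1-PA regions without JQ1-TCO were chromosome 10, 42395794 to 42397069 and 42388174 to 42388687, and chromosome 7, 61970206 to 61970593, with lower percentiles of 84.44, 69.56 and 72.86. All 3 overlap a peak of unmodified JQ1. They were followed by chromosome 1, 143278631 to 143279115 (39.62), and chromosome 2, 232044193 to 232044454 (38.88).

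The last comparison set unmodified JQ1 against the clickable molecules. Of its 142 peaks, 65 overlapped JQ1-PA replicate 1 (45.8%, interval 37.4 to 54.3%), 42 overlapped JQ1-PA replicate 2 (29.6%, 22.2 to 37.8%), 32 overlapped JQ1-TCO replicate 1 (22.5%, 16 to 30.3%) and 31 overlapped JQ1-TCO replicate 2 (21.8%, 15.3 to 29.5%). Shifted lists gave means of 1.26 to 2.92%. No clickable library overlapped 51 of the 142, and 42 overlapped JQ1-PA replicate 1 alone. Of the clickable lists, only that of JQ1-PA replicate 1 has the 5-column layout of the unmodified JQ1 list. Its higher overlap therefore cannot be told apart from a difference in how the lists were made. Seen from the other side, 0.291% of JQ1-PA replicate 1 peaks and 0.0472 to 0.0729% of the peaks of the other clickable lists overlapped an unmodified JQ1 peak. The highest-scoring JQ1 peak was chromosome 1, 121483868 to 121485616, which had a peak in all 4 clickable libraries. Chromosome 10 held 7 of the 10 highest, all between 42384056 and 42600471, and the other two below the first were chromosome 7, 61968613 to 61969775, and chromosome 1, 566233 to 566932, the latter without a peak in any clickable library. Joined over 1 Mb, the largest groups of JQ1 peaks were 15 on chromosome 10 (42360506 to 42600471), 15 on chromosome 19 (35788904 to 37786367) and 14 on chromosome 4 (49104355 to 49652857).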

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

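The tests in this part were chosen after the result was seen. A pair of sites, 782 bp and 875 bp wide, stood out in the fold enrichment column, which the comparisons did not use. At chromosome 19, 43167248 to 43168029, the authors' fold was 317.0 in JQ1-PA replicate 2, 228.2 in JQ1-TCO replicate 1 and 179.3 in JQ1-TCO replicate 2. At chromosome 3, 144517733 to 144518607, it was 323.7, 225.9 and 174.3. Unmodified JQ1 and JQ1-PA replicate 1 had no peak at either site.

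Near-identical copies of 1 sequence that share reads are a candidate explanation. The folds of the pair differed by 2.1%, 1.0% and 2.8% in the 3 libraries, whereas 39 of 1149 other pairs of high-fold regions that lay within 5% of each other in JQ1-PA replicate 2 (3.39%) did so in both JQ1-TCO libraries too. The sequences themselves were not compared here. Of the 100 highest-scoring peaks of JQ1-TCO replicate 2, 98 had a JQ1-PA replicate 1 peak and the 2 without one were this pair, but 10 of the 100 highest of JQ1-TCO replicate 1 and 24 of the 100 highest of JQ1-PA replicate 2 also lacked one; 10 of the 24 lay on contigs, where the JQ1-PA replicate 1 list holds no peaks. Probe binding common to all clickable libraries cannot be told apart from a difference in how the lists were made, because the background library is not stated.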

How the results depend on the processing

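Of 94 values under alternatives, 50 stayed within limits and 44 moved, the limits being the 95% interval of a share and 1.5 times for a count or ratio; the cause was not tested except where the alternative itself removes peaks or libraries. By construction, the upper 50% of each list by score held 71 unmodified JQ1 peaks, 12745 and 28879 JQ1-PA peaks and 30258 and 31792 JQ1-TCO peaks. Sharing under 50% overlap of both peaks, equal list length and the upper 50% by score was 37.5, 61.6 and 80.5% for JQ1-PA replicate 1 in replicate 2; 38, 77.2 and 93.7% for JQ1-PA replicate 1 in JQ1-TCO replicate 1; and 31.8, 82.9 and 96.9% in JQ1-TCO replicate 2. It was 27.3, 70.1 and 67.3% for JQ1-PA replicate 2 in JQ1-TCO replicate 1, 22.7, 72.4 and 70% in JQ1-TCO replicate 2, and 52, 83.3 and 82.2% between the JQ1-TCO libraries. Unmodified JQ1 peaks that overlapped any clickable library numbered 91 of 142, 56 with 50% overlap and 39 of 71 in the upper 50%, where the shorter list itself lowers the count. Regions of all 4 libraries numbered 5385 with 50% coverage and 13479 to 20780 with 1 library left out. Regions in JQ1-TCO without JQ1-PA numbered 2805 at equal list length and 17606 to 35831 with 1 library left out, and those in JQ1-PA without JQ1-TCO 137 and 94 to 27404. The highest, 27404, came without JQ1-PA replicate 1, when JQ1-PA needed a peak in 1 library and the JQ1-TCO count was 17606. Clusters shared by all among the first 100 numbered 23 to 41 with 1 library left out. Other stitching distances and ranking by summed score kept all cluster counts within 1.5 times. Chosen after seeing the data, the local shift of 100 kb lowered all 6 ratios of observed to shifted sharing, and chromosomes 1 to 22 and X gave 14147 and 61 regions of JQ1-TCO and JQ1-PA. Merging overlapping peaks changed nothing because no list held any. Promoter shares and gene lists were not run. No paired analysis was possible because only 1 of the JQ1-PA libraries carries a number in its label and no test between libraries was made.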

Other observations

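Beyond chromosomes 19 and 17, chromosomes 22 and 16 were dense in clickable peaks, at 1.72 to 1.96 and 1.64 to 1.8 times each library's mean density. Unmodified JQ1 stood at 2.12 and 1.93 times there, but on only 5 and 8 peaks. Of the 8 on chromosome 16, 6 lay between 32296787 and 33408980. JQ1-PA replicate 2 differed in peak width. Of its 57594 peaks, 17264 (29.98%) had the smallest width in the list, 213 bp, against 10.22 to 12.89% of peaks at the smallest width in the other clickable lists. Its 27326 regions without a peak in any other clickable library had a median width of 213 bp and a median score percentile of 32.7.

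The tests in the rest of this part were chosen after the results were seen. More regions were found in JQ1-TCO without JQ1-PA than the reverse. List length alone is argued against, since with 25397 peaks per library the JQ1-TCO count was 20.5 times the JQ1-PA count. That cut keeps the whole JQ1-PA replicate 1 list, so it matches length and not depth. At this length the JQ1-PA pair shared 61.6% and the JQ1-TCO pair 83.3%, so the ratio also reflects how well each pair agreed. An effect of JQ1-PA replicate 1 alone stays open: among the 3 other libraries, at 57594 peaks each, the JQ1-TCO pair had 9.4 times as many regions to itself as the larger mixed pair, but that sets pairs against pairs and not JQ1-TCO against JQ1-PA. A detection limit stays open: at most 0.07% of these regions were in the highest-scoring 10% of a JQ1-TCO list, which the sharing of the highest-scoring peaks already implies, and 30.5% and 49.9% of them were in the upper 50% of JQ1-TCO replicates 1 and 2. The click handle cannot be told apart from chance or protocol, because the 14229 regions that split by compound come from 1 of only 3 possible splits.

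Many unmodified JQ1 peaks lay within 5 Mb of the widest stretch of their chromosome without a clickable peak, or in it: 58.5% (interval 49.9 to 66.7%), against 7.31% of the chromosome length outside the stretches. A few groups carried much of this, with 15 of 16 peaks on chromosome 10 and 14 of 16 on chromosome 4 but 2 of 18 on chromosome 19. Without those that reach into a stretch, which clickable peaks cannot do by its definition, 12 of 45 groups of peaks joined over 1 Mb (26.7%, 14.6 to 41.9%) lay within 5 Mb, which argues against even placement. Of the 142 unmodified JQ1 peaks, 16 lay in regions of all 4 clickable libraries (11.3%, 6.58 to 17.7%). Carry-over of those regions alone would leave most of the peaks unexplained. Those regions cover only 20.64 Mb and no shifted share was computed for them, so carry-over stays open for these 16. Carry-over of sites found in fewer libraries was not tested and also stays open. At least 1 clickable library overlapped 91 of the 142, and JQ1-PA replicate 1 alone overlapped 42. Sequence bordering the gaps of the assembly stays open, with 41.5% of peaks but 6 of the 45 groups (13.3%, 5.05 to 26.8%) within 1 Mb against 1.48% of that length, and no biological explanation was tested.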
